A study of Homo sapiens with 48 samples.

How the data were processed

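Polyadenylated RNA of H9 human embryonic stem cells (passage 57) was sequenced in 48 libraries: 12 of wild-type cells, 24 of 2 ALKBH5 knockout lines and 12 of 2 DKK4 knockout lines, in 24 groups of 2. According to the labels, cells were kept in mTeSR1 and moved to an endoderm induction medium, and messenger RNA was enriched with oligo-dT beads and copied with random hexamers. Per the labels, the authors demultiplexed the reads, aligned them to hg38 with Bowtie2 2.2.5 and estimated expression with RSEM 1.3.0. The deposited values are expression scores in whole numbers that sum to nearly the same total in each library, as TPM does, and the step that made them whole numbers is not given in the sources used here. They are not counts, so the depth of a library is unknown and no interval or floor from counting was computed. A length check was made on the values: across 14643 genes log2 value and log2 transcript length correlated at -0.161, with genes not being independent replicates.

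The table held 57237 lines. Of these, 12 blank lines, 1 with a missing value and 45 that repeated a gene were left out, and 57179 genes were kept. All identifiers were found in GENCODE release 29, and 37154 genes had the same coordinates there. In 14 cases a symbol had been turned into a date, and the symbol of the annotation was used. Genes with a value of at least 1 in at least 2 libraries were tested, 21164 in all.

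Values were taken as log2(value + 1) without further scaling. A linear model with a mean for each of the 24 groups was fitted over all 48 libraries with limma 3.58.1 (statmod 1.5.0, R 4.3.3), which left 24 residual degrees of freedom, and the spread of each gene was moderated with a trend on its level and a robust prior. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method over the 21164 genes of each comparison. In a comparison with a knockout the means of KO1 and KO2 were averaged. A gene was called where adjusted p was below 0.05 and both lines differed in the same direction, or, between the knockouts, where each ALKBH5 line differed from each DKK4 line in the same direction. Each knockout was compared with wild type at each stage, wild-type stages with day 0 and between arms, and the ALKBH5 effect between arms and between day 3 and day 0 as a difference of differences. Both knockouts were compared directly at day 1 and day 3 of arm A.

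The 23 gene lists were written before the data were examined: pluripotency, primitive streak, definitive endoderm, mesoderm, late endoderm, neuroectoderm, trophoblast and amnion, blood and endothelium, fibroblast, WNT targets, WNT antagonists, WNT ligands, NODAL targets, BMP targets, epithelial, mesenchymal, m6A machinery, p53 targets, cell cycle, integrated stress response, mitochondrial mRNA, HOX genes and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, and p was adjusted over the lists of a comparison. Genes named in the report follow a rule written before the data were examined. It takes fixed markers, the 5 called genes with the largest rise and the 5 with the largest fall in each comparison with a mean of at least 5 in the higher group, and up to 4 members of each list with the smallest adjusted p, and in comparisons with wild type the largest changes had to be called in each line alone. Other genes named, RPS28P7 and those of the library sets among them, were chosen after their values were seen. The result of 1 gene that the rule selects is not reported here.

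The method was tested on simulated data with the spread of these libraries. In these, 200 of 21164 genes were changed, all of them genes with a mean of 5 or more. At a log2 change of 0.585 it recovered 44% of them in the ALKBH5 comparison at day 3 of arm A, 41.5% in the DKK4 comparison and 59% in the direct one, so many changes under 2-fold are missed. At a log2 change of 1 it recovered 81.5% of them in the ALKBH5 comparison at day 3 of arm A, 81% in the DKK4 comparison and 92% in the direct one. At a log2 change of 2 the shares were 98%, 96% and 98.5%. Recovery of changes in genes with a mean under 5 was not measured. Up to 22.1% of calls were false, most of them genes with a mean under 5: of 46 false calls 41 were such genes and 5 had a mean of 5 or more, out of 10589 genes at that level. The adjusted p of genes at low values is therefore less reliable than its value states.

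The alternatives tried were median-of-ratios scaling, no filter, a pseudocount of 0.1, a replicate block, the libraries of a comparison alone, each line alone, adjusted p below 0.01 and each library left out in turn. Alternatives added after the data were examined were a minimum value of 5, a fit without the DKK4 libraries, differences taken beyond day 0 or day 1, and the settings of the genes changed in both knockouts. Count-based tests were not run, since the values are not counts. Replicate numbers were checked for pairing over 276 pairs of groups, and the correlations of replicate differences lay between -0.0771 and 0.0707, so libraries were not paired. Symbols of overlapping or near-identical genes, such as MT-ATP8, HIST1H4K, F8A2, RPL36A and HBA2, depend on how reads were assigned, and their values are uncertain.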

Results

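RNA was sequenced from H9, a human embryonic stem cell line, before and during culture in a medium that induces definitive endoderm, the germ layer that gives rise to gut, liver and pancreas. The 48 libraries form 24 groups of 2. They come from wild-type cells, from 2 lines in which ALKBH5 was knocked out and from 2 lines in which DKK4 was knocked out, each pair named KO1 and KO2. ALKBH5 encodes a demethylase that removes N6-methyladenosine from RNA, and DKK4 encodes a secreted antagonist of WNT signalling. Wild-type and ALKBH5 knockout cells were sampled undifferentiated (day 0), at day 1, 36 h and day 3 of an arm named A, and at day 1 and day 3 of an arm named C. The DKK4 knockout lines were sampled at day 0, day 1 and day 3 of arm A. Their day 0 titles carry the letter A and the other day 0 titles do not, though all are labelled undifferentiated. The labels do not say how arms A and C differ, or whether the libraries of a group came from separate cultures. The p-values therefore measure the spread between the 2 libraries of a group, part of which may be technical. The spread between the 2 lines of a knockout does not enter them. At day 3 of arm A the lines differed from each other at 1527 genes for ALKBH5 and 1111 for DKK4.

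The values are whole numbers on a TPM-like scale, and each library summed to between 988059 and 989753, so the number of reads behind a value is unknown. Each library listed between 14538 and 16417 genes at 1 or more, and the 4 DKK4 knockout libraries of day 0 listed the most, 16232 to 16417. The replicates of a group correlated across genes at 0.97 to 0.98. Values below are means ± SD over 2 wild-type libraries and over the 4 libraries of both lines of a knockout. A gene is said to have risen or fallen where limma's adjusted p was below 0.05 and both lines moved that way. Log2 changes are on the scale of log2(value + 1), which understates the change of genes at low values. Counts within a gene list are also given adjusted over the list alone, and the call of limma's camera test of a list held with an estimated correlation unless a second p is given.

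The libraries also fell into 2 sets that the labels do not name. In 18 libraries, RPL36A, a ribosomal protein gene, lay between 1867 and 3083, against 435 to 813 in the other 30. RPS28P7, a processed pseudogene, lay between 31 and 1364 in the same 18 libraries and between 2783 and 8113 in the others, and HIST1H4K was listed at 0 in all 18 and at 53 to 327 elsewhere. The set held the 6 libraries of 36 h, wild type and ALKBH5 knockout, and all 12 DKK4 knockout libraries. Among 6318 genes with a mean of 20 or more, 19 separated the sets in full, and 52.6% of these were ribosomal protein genes or processed pseudogenes, against 1.69% of all 6318. Each comparison of an ALKBH5 knockout with wild type of the same stage lay within a single set. Every comparison of a DKK4 knockout with wild type or with the ALKBH5 knockout, and that of wild-type 36 h with day 0, crossed the sets. The set holds wild-type cells only at 36 h, so within these comparisons the set and the group cannot be told apart.

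**Figure D1:**
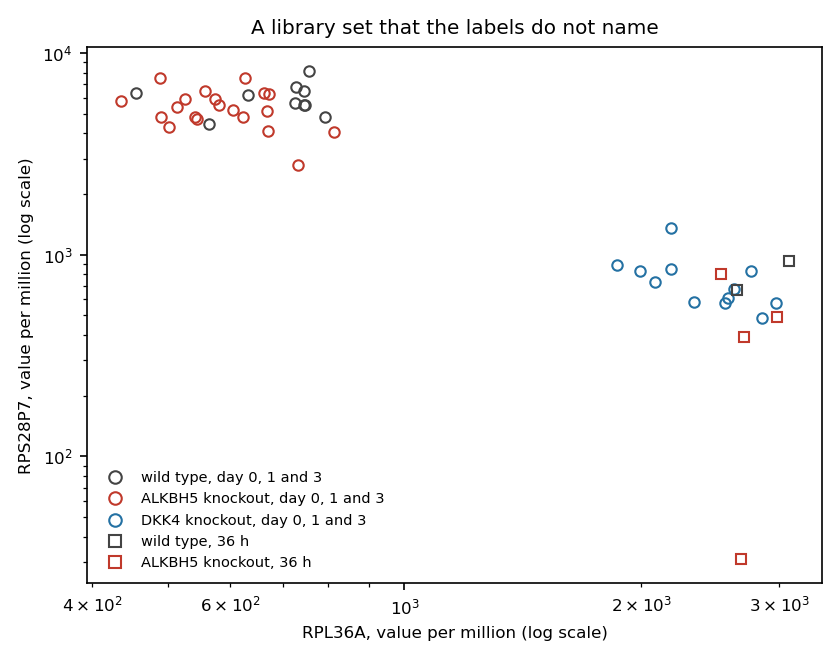
TPM-like value of RPL36A (horizontal, log scale) and of RPS28P7 (vertical, log scale) in each of the 48 libraries, 1 point per library, coloured by genotype, with squares for 36 h. The 18 libraries of the DKK4 knockout lines and of 36 h lie at 1867 or more for RPL36A, and the other 30 at 813 or less.

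The wild-type course through arm A answers which genes mark each stage in the cells that the knockouts are compared with. At day 1 the primitive streak genes CER1, MIXL1 and EOMES rose first: CER1 from 2 ± 0 to 173 ± 2.83, MIXL1 from 1 ± 0 to 31 ± 0, and EOMES from 0 in both libraries to 24.5 ± 0.707. LEFTY2, a target and antagonist of NODAL signalling, went from 25.5 ± 3.54 to 791 ± 8.48. At 36 h EOMES stood at 493 ± 11.3, TBXT at 28.5 ± 0.707 and DKK4, listed at 0 until then, at 345 ± 1.41. At day 3 the endoderm factors SOX17 (502 ± 25.5), GATA6 (183 ± 29.7) and FOXA2 (89 ± 8.48) were high, all listed at 0 at day 0, and CXCR4, a surface marker of endoderm, had gone from 1 ± 0 to 136.5 ± 7.78. POU5F1, a core pluripotency factor, fell from 2155 ± 123 to 1320 ± 115.

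By list, 10 of 19 primitive streak genes rose at day 1 and 14 rose and 1 fell at day 3, the same counts adjusted over the list alone (limma camera adjusted p = 4.58e-21 and 1.57e-19). Of 20 definitive endoderm genes 18 rose and 2 fell by day 3, as adjusted over the list alone (limma camera adjusted p = 2.02e-32). Of 20 pluripotency genes 15 fell, DNMT3B from 837.5 to 162 and TERF1 from 501.5 to 96 among them, again as adjusted over the list alone (limma camera adjusted p = 1.26e-14). The cell cycle list had 2 genes that rose and 13 that fell (4 and 13 adjusted over the list alone), with MCM3 down from 255 to 93 (limma camera adjusted p = 7.22e-05). The metallothionein genes MT1X and MT1G, which bind metal ions, fell from 320.5 ± 43.1 and 382.5 ± 37.5 to 1.5 ± 0.707 and 6 ± 5.66.

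Across all 21164 genes tested, 675 rose and 1513 fell at day 1, 2322 rose and 3387 fell at 36 h, and 2905 rose and 3759 fell at day 3, the last 3050 and 2775 without replicate 2 of wild-type arm A day 3. After median-of-ratios scaling the day 1 split was 898 and 1161. The day 1 count of 2188 was 1254 without replicate 1 of wild-type arm A day 1 and 1283 without replicate 2 of wild-type day 0. Fits to the compared libraries alone, here and below, take their own spread and also test fewer genes, and they called 300 genes at day 1, 3068 at 36 h and 2595 at day 3. Of 73 genes that stood apart at 36 h from day 1 and day 3 in both ALKBH5 knockout lines, 51 were called in that direction between wild-type 36 h and day 0 and 0 against it, which the library set and a passing change of the cells at 36 h would both give.

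Arm C reached the same markers by a different course. At its day 1 wild-type cells already held MIXL1 at 1335 ± 63.6, TBXT at 85.5 ± 3.54, DKK4 at 306.5 ± 47.4 and the WNT target SP5 at 512 ± 41, against 31 ± 0, 3 ± 0, 0 in both libraries and 14 in arm A. LEFTY1 went the other way, with 180.5 ± 6.36 in arm C and 2335 ± 55.1 in arm A. At day 3 SOX17 stood at 742.5 ± 3.54 and CXCR4 at 409 ± 35.4, above arm A by 0.56 ± 0.14 and 1.57 ± 0.23 (SE) on the log2 scale, while DKK4 had dropped to 2 ± 0, against 515 ± 181 in arm A. APOA2 and HNF4A, genes of the later liver programme, stood at 137.5 and 4, against 12 and 0 in arm A.

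By list, WNT targets were higher in arm C at day 1, with 14 of 19 up and 0 down (15 and 0 adjusted over the list alone; limma camera adjusted p = 3.69e-11). Of 21 p53 targets 16 were higher (18 adjusted over the list alone), with CDKN1A, an inhibitor of the cell cycle, at 69 against 2 (limma camera adjusted p = 1.91e-15). Of 13 WNT ligands 4 were higher, also adjusted over the list alone, WNT3 at 33.5 against 10 among them (limma camera adjusted p = 0.0373, and adjusted p = 0.0831 with an estimated correlation). At day 3, 23 of 24 cell cycle genes were lower in arm C, also adjusted over the list alone (limma camera adjusted p = 7.62e-33). There 11 of 20 definitive endoderm genes were higher (12 adjusted over the list alone; limma camera adjusted p = 5.33e-14), as were 4 of 9 late endoderm genes (5 adjusted over the list alone; limma camera adjusted p = 3.47e-04).

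Against day 0, 1551 genes rose and 2268 fell at day 1 of arm C, and 3168 rose and 5055 fell at day 3. Between the arms, 2407 genes were higher and 1881 lower in arm C at day 1, and 1399 and 2570 at day 3. After median-of-ratios scaling the split was 4037 and 4210 for day 3 against day 0, and for arm C against arm A it turned to 2139 and 2218 at day 1 and was 1964 and 2071 at day 3. Fits to the compared libraries alone called 1575, 5384, 2474 and 549 genes in these 4 comparisons.

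The ALKBH5 comparisons ask what loss of the demethylase changes before and during endoderm induction. ALKBH5 (chromosome 17, 18183078 to 18209398) was low in every knockout library: between 2 and 13 in all 24, against 36 to 61 in the 12 wild-type libraries, and 34 to 52 in the 12 DKK4 knockout libraries. KO2 held less of it than KO1, for example 3 against 10 at day 0.

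In undifferentiated cells the knockout changed few genes, and the core pluripotency factors kept their levels: POU5F1 stood at 1896 ± 81 against 2155 ± 123 and NANOG at 44.5 ± 5.8 against 42.5 ± 0.707, neither past the test. LEFTY1 fell from 121.5 ± 12 to 60.75 ± 9.29. VIM, an intermediate filament gene of mesenchymal cells, rose from 445 to 777.5. CTSF, a lysosomal protease gene, fell from 9.5 ± 0.707 to values of 0 or 1. CYP4F22 was listed at 0 in both wild-type libraries and at 5 to 9 in the knockout.

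Of 15 genes of the integrated stress response, which raises amino acid synthesis and chaperones, 4 rose (7 adjusted over the list alone), ASNS from 83 to 117 and PSAT1 from 258.5 to 314.5 among them (limma camera adjusted p = 1.02e-07). Of 24 cell cycle genes 5 fell (9 adjusted over the list alone), MCM5 from 240 to 178.5 (limma camera adjusted p = 4.96e-07). Of 14 mesenchymal genes 4 rose, also adjusted over the list alone (limma camera adjusted p = 5.87e-04). Of 13 mitochondrial mRNAs 6 rose (10 adjusted over the list alone), MT-ND1 from 2498 to 3780 (limma camera adjusted p = 5.54e-12, and adjusted p = 0.0763 with an estimated correlation).

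In all, 265 genes rose and 154 fell at day 0, of them 67 and 31 by 2-fold or more. Without replicate 1 of wild-type day 0 the balance turned, with 102 up and 159 down, 261 in all against 419, and 140 genes were called both with and without it in the same direction. The count was 57 in a fit to these libraries alone and 248 with KO2 alone, and without a filter 280 genes rose and 267 fell.

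In arm A the knockout cells did not reach the endoderm state. At day 3 SOX17 was listed at 0, 0, 3 and 4 in the knockout libraries, against 502 ± 25.5 in wild type, and FOXA2 at 0, 0, 1 and 1, against 89 ± 8.48. GATA6 (chromosome 18, 22169392 to 22202528) stood at 3.25 ± 1.71 against 183 ± 29.7, DKK4 at 0, 0, 4 and 5 against 515 ± 181, and FGF17, a growth factor gene of endoderm, at 8.75 ± 9.32 against 1640 ± 20.5. POU5F1 and SOX2 stayed higher, at 2390 ± 121 and 153.2 ± 24.6 against 1320 ± 115 and 84 ± 8.48. SPP1, which encodes the matrix protein osteopontin, stood at 1748 ± 873 against 4.5 ± 0.707, and ANXA1 at 773 ± 218 against 5 ± 1.41. GREM1, a secreted BMP antagonist, was listed at 0 in both wild-type libraries and stood at 48 to 94 in the knockout.

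The difference opened before day 3. At day 1 EOMES was listed at 0, 1, 2 and 2, against 24.5 ± 0.707 in wild type, and MIXL1 stood at 7.75 ± 1.26 against 31 ± 0. CHAC1, a stress response enzyme gene, was already at 66 ± 12.4 against 11 ± 0. At 36 h, where all 6 libraries belong to the same set, EOMES stood at 15 ± 15.1 against 493 ± 11.3 and MIXL1 at 18.75 ± 13.2 against 746.5 ± 3.54. GATA6 and SOX17 were listed at 0 in all 4 knockout libraries, against 32.5 ± 2.12 and 11.5 ± 0.707, and DKK4 at 0, 0, 2 and 6 against 345 ± 1.41. AXIN2, a target of WNT signalling, rose at day 1, from 5.5 ± 0.707 to 11.25 ± 3.3, and then fell at 36 h, from 34.5 ± 0.707 to 12.75 ± 0.957.

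By list, 8 of 19 primitive streak genes fell and 1 rose at day 1 (9 and 1 adjusted over the list alone; limma camera adjusted p = 5.51e-11), and 17 fell at 36 h, also adjusted over the list alone, with a median of -3.05 on the log2 scale (limma camera adjusted p = 2.53e-39). Of 20 definitive endoderm genes 19 fell and 1 rose at day 3, also adjusted over the list alone, with a median of -3.92 (limma camera adjusted p = 8.47e-23). Of 20 pluripotency genes 13 rose and 3 fell (15 and 3 adjusted over the list alone), FGF2 from 11 to 51.25 and ZFP42 from 55 to 127.5 (limma camera adjusted p = 6.81e-06). Of 19 WNT targets 10 fell and 2 rose at day 3, also adjusted over the list alone, with DKK1 down from 14 to 1.25 and BAMBI up from 31.5 to 79.75 (limma camera adjusted p = 0.00985, and adjusted p = 0.0648 with an estimated correlation). At 36 h 11 of them fell and 1 rose (12 and 1 adjusted over the list alone; limma camera adjusted p = 1.04e-07). WNT antagonists fell too, 9 of 15 at day 3 with 3 up, also adjusted over the list alone, CER1 from 4740 to 301.5 and SFRP1 from 285 to 34.5 (limma camera adjusted p = 4.16e-05). Of 12 NODAL targets 8 fell and 3 rose at day 3 (8 and 4 adjusted over the list alone; limma camera adjusted p = 0.00173).

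Among the other lists, integrated stress response genes rose in 14 of 15 cases at day 1 and 13 of 15 at day 3, also adjusted over the list alone, TRIB3 from 8 to 51 and ASNS from 108 to 297.8 at day 3 (limma camera adjusted p = 3.68e-28 and 5.95e-11). All 8 fibroblast genes tested rose at day 3, also adjusted over the list alone, TAGLN from 829 to 3334 and THY1 from 52.5 to 261.2 (limma camera adjusted p = 6.16e-07). Of 12 trophoblast and amnion genes 6 rose and 0 fell, also adjusted over the list alone, TFAP2C from 3 to 25.5 among them (limma camera adjusted p = 0.00495), and of 12 neuroectoderm genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), NES from 67.5 to 422.8 up and SIX3 to 0 in all 4 knockout libraries (limma camera adjusted p = 0.00745). Epithelial genes rose in 8 of 14 cases at 36 h and fell in 0 (9 and 0 adjusted over the list alone; limma camera adjusted p = 3.16e-07). Of 19 mesoderm genes 5 rose and 3 fell at day 3 (6 and 5 adjusted over the list alone; limma camera adjusted p = 0.114), and of 11 blood and endothelium genes 4 rose and 1 fell (4 and 2 adjusted over the list alone; limma camera adjusted p = 0.127). Of 23 genes of the m6A machinery 7 rose and 6 fell, ALKBH5 among them (8 and 7 adjusted over the list alone; limma camera adjusted p = 0.981). Of 82 ribosomal protein genes 4 rose and 51 fell (5 and 52 adjusted over the list alone; limma camera adjusted p = 1.12e-06, and adjusted p = 0.313 with an estimated correlation). None of the 39 HOX genes reached the level needed for testing.

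In all, 1268 genes rose and 621 fell at day 1, 1474 and 1485 at 36 h, and 3655 and 4327 at day 3, where 1589 and 1943 of them moved by 2-fold or more. Without replicate 1 of wild-type arm A day 3 the day 3 split was 3508 and 3173. After median-of-ratios scaling the split was 1109 and 832 at day 1 and 1695 and 1311 at 36 h. The day 1 count of 1889 was 797 and 1166 without replicate 1 or replicate 2 of wild-type arm A day 1 and 821 with KO2 alone, and the 36 h count of 2959 was 1836 without replicate 2 of wild-type 36 h. At day 3 the lines differed from each other at 1527 genes.

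**Figure D2:**
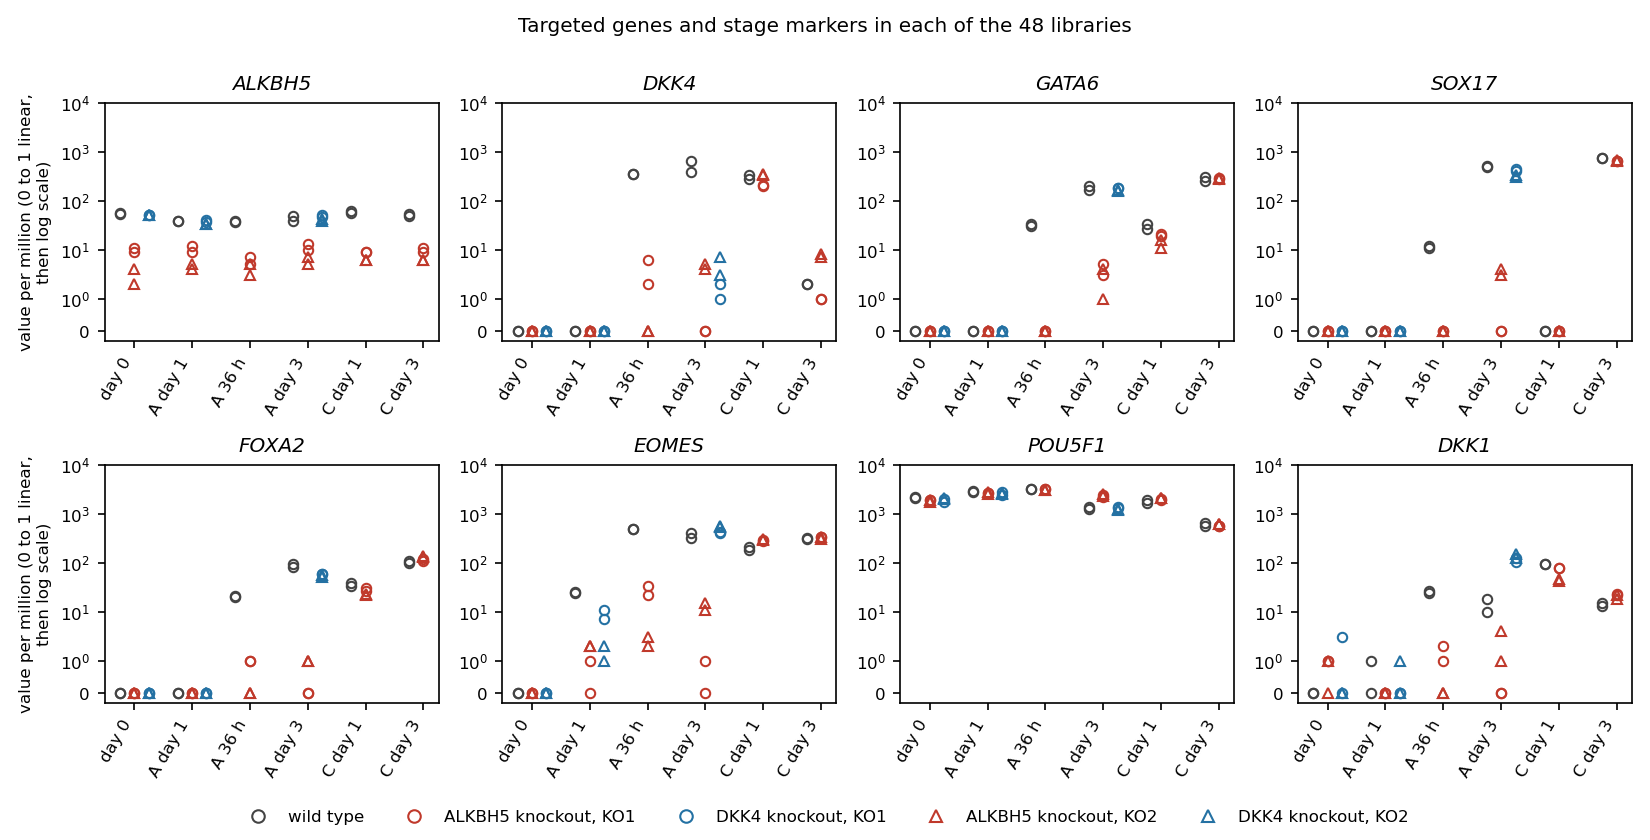
TPM-like value of ALKBH5, DKK4, GATA6, SOX17, FOXA2, EOMES, POU5F1 and DKK1 (vertical axis, linear from 0 to 1 and logarithmic above) in each of the 48 libraries, placed by arm and stage, with circles for wild type and KO1 and triangles for KO2. At day 3 SOX17 lies at 0 to 4 in the ALKBH5 knockout in arm A, at 310 to 444 in the DKK4 knockout in arm A, and at 651 to 679 in the ALKBH5 knockout in arm C.

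In arm C the same knockout lines did reach the endoderm markers. At day 3 SOX17 stood at 661.8 ± 12.2 against 742.5 ± 3.54 in wild type, FOXA2 at 124.5 ± 11.1 against 103 ± 5.66, and GATA6 at 286.8 ± 7.41 against 273.5 ± 37.5, none of them past the test. None of 20 definitive endoderm genes rose or fell, also adjusted over the list alone. The genes that did change were others: MT1G was listed at 0 in both wild-type libraries and stood at 17.25 ± 4.99 in the knockout, CD48 fell from 99.5 ± 20.5 to 34.5 ± 10.2, and ACTN3, a muscle actinin gene, from 13.5 ± 4.95 to 4.25 ± 1.5. Of 24 cell cycle genes 14 rose and 0 fell (15 adjusted over the list alone), MCM2 from 29 to 47.75 among them (limma camera adjusted p = 2.54e-16).

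At day 1 of arm C, DKK4 stood at 271.8 ± 79.7 against 306.5 ± 47.4, not past the test, while GATA6 fell from 30 ± 5.66 to 16.75 ± 4.35 and FOXA2 from 36 ± 2.83 to 25.5 ± 4.04. The WNT targets AXIN2 and LEF1 rose, from 20.5 ± 0.707 to 50 ± 17.4 and from 2.5 ± 2.12 to 7.25 ± 1.5. CDKN1A fell from 69 ± 7.07 to 10.75 ± 3.2 and FOSL1, a transcription factor gene of the AP-1 family, from 46.5 ± 2.12 to 6.5 ± 1. Of 21 p53 targets 15 fell and 0 rose (20 and 0 adjusted over the list alone; limma camera adjusted p = 1.78e-23). Of 15 integrated stress response genes 9 fell and 0 rose (10 and 0 adjusted over the list alone), CHAC1 from 52 to 16.5, the reverse of arm A (limma camera adjusted p = 4.48e-12). Of 12 BMP targets 4 fell and 0 rose, also adjusted over the list alone, ID3 from 212.5 to 144 (limma camera adjusted p = 0.00162). HIST1H4A, listed at 7 ± 1.41 in wild type and at 0 in the knockout, shares its sequence with other histone genes and is uncertain.

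In all, 768 genes rose and 875 fell at day 1 of arm C, and 831 rose and 274 fell at day 3, the latter 540 and 438 after median-of-ratios scaling. The day 1 count of 1643 was 905 and 1042 without replicate 1 or replicate 2 of wild-type arm C day 1. The day 3 count of 1105 was 574 without replicate 2 of wild-type arm C day 3, 733 without replicate 2 of KO2, 1825 with KO1 alone, 286 with KO2 alone and 408 in a fit to these libraries alone.

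The difference between the arms was tested itself. The knockout effect at day 3 was higher in arm C than in arm A by 7.73 ± 0.18 (SE) on the log2 scale for SOX17, 8.20 ± 0.35 for DKK4 and 5.61 ± 0.30 for GATA6 (limma, adjusted p = 6.62e-24, 1.75e-17 and 4.41e-15), and lower by 6.40 ± 0.27 for SPP1. DKK4 was at 2 in both wild-type libraries of arm C day 3, so a fall could hardly be seen there. Its difference between the arms therefore rests on the fall in arm A. Of 20 definitive endoderm genes 19 differed upwards and 1 downwards, also adjusted over the list alone (limma camera adjusted p = 1.18e-28). At day 1 the effect was higher in arm C by 4.22 ± 0.32 for EOMES and lower for CHAC1 and CDKN1A (limma, adjusted p = 6.75e-11, 1.49e-15 and 2.09e-08). Of 15 integrated stress response genes 13 differed downwards at day 1, also adjusted over the list alone (limma camera adjusted p = 6.76e-31).

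In all, the effect differed between arms at 632 genes upwards and 1147 downwards at day 1, and at 2944 and 2076 at day 3, the latter 2393 and 2578 after median-of-ratios scaling. Between day 3 of arm A and day 0 it differed at 2668 genes upwards and 2843 downwards, or 2857 and 2798 after median-of-ratios scaling and 2704 and 2236 without replicate 1 of wild-type arm A day 3. The day 1 count of 1779 was 1099 without replicate 1 of wild-type arm A day 1.

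**Figure D3:**
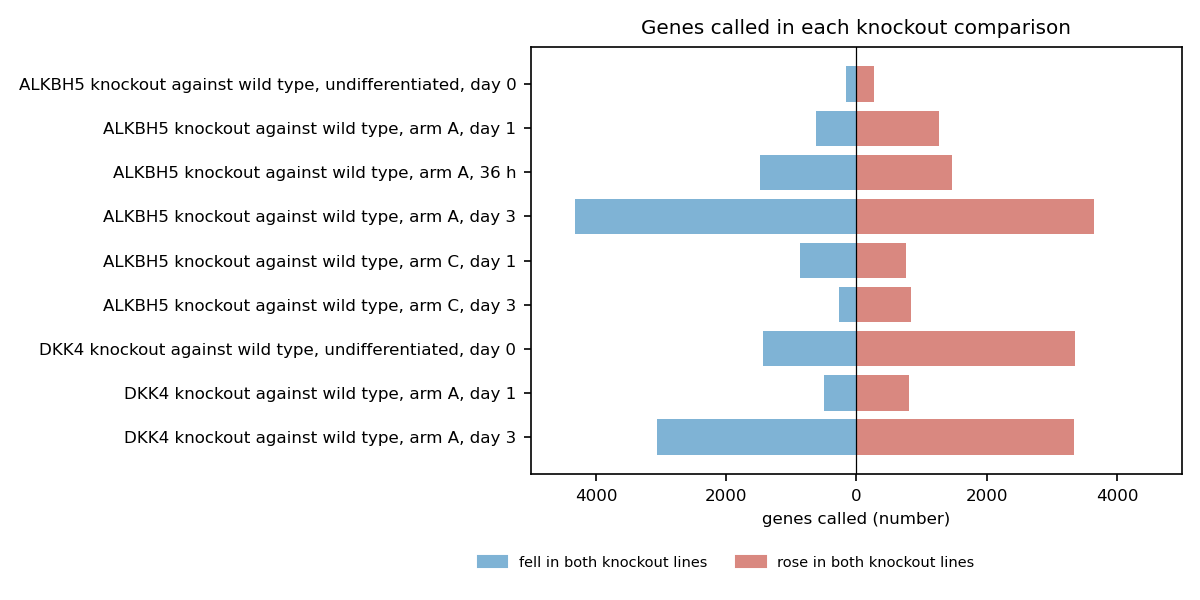
Number of genes that rose (right, red) or fell (left, blue) in each comparison of a knockout with wild type, out of 21164 tested. The ALKBH5 knockout bars reach 3655 and 4327 at day 3 of arm A and 831 and 274 at day 3 of arm C.

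The DKK4 comparisons ask what loss of this WNT antagonist changes along arm A, with the knockout libraries in the set of 18 and the wild-type libraries outside it. DKK4 (chromosome 8, 42374063 to 42377229) was listed at 0 in every library of day 0 and of day 1 of arm A, wild type included, so its knockout can be seen only at day 3. There DKK4 stood at 1, 2, 3 and 7 in the knockout libraries, against 515 ± 181 in wild type. The differences of the DKK4 lines at day 0 and day 1 were thus measured before any DKK4 RNA was listed.

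At day 0 the DKK4 lines still differed from wild type at many genes. DDIT4 and TXNIP, stress-regulated genes, rose from 34.5 ± 2.12 to 325.5 ± 19.8 and from 6 ± 1.41 to 69.5 ± 6.61, DDIT3, a transcription factor gene of the stress response, from 2.5 ± 0.707 to 44 ± 4.69, and CUZD1 from 3 ± 0 to 76.75 ± 21.2. HSPA1A, a heat shock chaperone gene, fell from 42 ± 1.41 to 7.75 ± 2.63. Of 15 integrated stress response genes 12 rose and 2 fell, also adjusted over the list alone, ASNS from 83 to 320.8 and TRIB3 from 12.5 to 80.5 (limma camera adjusted p = 1.26e-11). Of 24 cell cycle genes 9 fell and 2 rose (9 and 4 adjusted over the list alone; limma camera adjusted p = 1.33e-04, and adjusted p = 0.116 with an estimated correlation). The largest falls, HIST1H4K from 138.5 to 0 among them, include genes that separate the library sets.

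At day 1 EOMES fell from 24.5 ± 0.707 to 5.25 ± 4.65 and MIXL1 from 31 ± 0 to 16 ± 5.35. Of 19 primitive streak genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; limma camera adjusted p = 1.28e-07), and of 12 BMP targets 4 fell and 0 rose (6 and 0 adjusted over the list alone), ID1 from 599.5 to 294.5 (limma camera adjusted p = 1.28e-07). Beyond the day 0 difference EOMES and MIXL1 were still lower, by -2.38 and -1.66 on the log2 scale, while ID1 was higher by 0.58, all past the test. At day 0 EOMES was listed at 0 and MIXL1 at 1 to 3 in these lines, so the subtraction holds little information for them. GCNT4 rose from 2 ± 0 to 10.5 ± 1.73 and ANXA3 from 18 ± 1.41 to 53.5 ± 8.81, and RPL36A, from 734.5 ± 13.4 to 2539 ± 453, is a gene of the library set. The rise of ANXA3 did not pass the test beyond day 0.

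At day 3 the DKK4 lines held the endoderm factors at or somewhat below wild type. GATA6 stood at 172 ± 8.76 against 183 ± 29.7, not past the test, SOX17 fell from 502 ± 25.5 to 373.2 ± 61.3, FOXA2 from 89 ± 8.48 to 56 ± 4.32 and CXCR4 from 136.5 ± 7.78 to 68 ± 8.29. The fall of SOX17 did not pass the test in KO1 alone. It also did not beyond the day 0 or day 1 difference, nor did that of CXCR4 beyond day 0. SOX17 was listed at 0 in all wild-type and DKK4 libraries of day 0 and of arm A day 1. Its change beyond these stages is therefore the same, and only its spread is larger. CXCR4 was listed at 0 or 1 in these lines at day 0. These lost calls do not show that the falls were present earlier. Some WNT targets, 9 of 19, rose: DKK1 from 14 ± 5.66 to 125.8 ± 17.7, AXIN2 from 12.5 ± 3.54 to 35 ± 6.48, and TBXT from 0 in both wild-type libraries to 4, 5, 5 and 8. NANOG rose from 34 ± 0 to 87 ± 6.05 and SOX2 fell from 84 ± 8.48 to 48 ± 7.12. NANOG was already at 60 to 76 in the DKK4 lines at day 0, against 42 and 43, and beyond the day 0 difference its log2 rise was 0.64 in place of 1.33. ANXA1, which rose in the ALKBH5 knockout, rose here as well, from 5 ± 1.41 to 108 ± 54.9.

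By list, the 9 WNT targets that rose at day 3 stand beside 1, DKK4 itself, that fell (11 and 2 adjusted over the list alone; limma camera adjusted p = 0.0067, and adjusted p = 0.0771 with an estimated correlation). Of 20 definitive endoderm genes 9 fell and 3 rose (11 and 4 adjusted over the list alone), LEFTY2 from 907.5 to 229.5 (limma camera adjusted p = 0.00658, and adjusted p = 0.0771 with an estimated correlation). Cell cycle genes rose in 15 of 24 cases and fell in 0 (19 and 0 adjusted over the list alone; limma camera adjusted p = 2.89e-07), and integrated stress response genes in 11 of 15 (13 adjusted over the list alone; limma camera adjusted p = 1.75e-07). Mesenchymal genes rose in 10 of 14 cases and fell in 3 (11 and 3 adjusted over the list alone), CDH2 from 187 to 359.8 (limma camera adjusted p = 0.0013). Of 21 p53 targets 12 fell and 0 rose (13 and 2 adjusted over the list alone; limma camera adjusted p = 1.21e-05). They include BAX, from 393.5 to 142.5, which separates the library sets, and PHLDA3, from 58 to 15. Beyond the day 1 difference the log2 falls of BAX and PHLDA3 were -0.74 and -1.02 in place of -1.46 and -2.07, and the rise of CDH2 did not pass the test.

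In all, 3361 genes rose and 1429 fell at day 0, 814 and 500 at day 1, and 3347 and 3069 at day 3. After median-of-ratios scaling the splits were 2228 and 2226 at day 0, 610 and 756 at day 1 and 3026 and 3396 at day 3, and the scaling moved the day 0 median of all genes from 0.146 to 0.00967 on the log2 scale. A shift between library sets that is the same at each stage drops out of a difference of differences only for genes well above 0. For a gene near 0 at 1 of the stages it need not, on the scale of log2(value + 1). Beyond the day 0 difference 1243 genes were called at day 1 and 5151 at day 3. Of these, 196 and 3320 had been called before in the same direction. Beyond the day 1 difference 2688 were called at day 3, 2382 of them called before in the same direction. The day 0 count of 4790 was 2736 without replicate 1 of wild-type day 0 and 3077 in a fit to these libraries alone. The day 3 split was 1829 and 2545 without replicate 2 of wild-type arm A day 3. The day 1 count of 1314 was 471 without replicate 1 of wild-type arm A day 1, with the balance turned to 198 up and 273 down, 681 without its replicate 2, 793 without replicate 2 of DKK4 KO2 and 829 with KO1 alone.

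The direct comparison of the knockouts asks where loss of ALKBH5 and loss of DKK4 differ, again across the library sets. At day 3 SOX17 was at 0 to 4 in the ALKBH5 lines and at 373.2 ± 61.3 in the DKK4 lines, lower by a log2 change of -7.45 ± 0.10 (SE), and EOMES, DKK1 and FGF17 were lower by -6.76 ± 0.18, -6.14 ± 0.31 and -7.64 ± 0.14 (limma, adjusted p = 2.23e-30, 5.20e-23, 1.52e-16 and 3.67e-27). DKK4 itself stood at 2.25 ± 2.63 in the ALKBH5 lines and 3.25 ± 2.63 in the DKK4 lines and was not called. SPP1 was higher in the ALKBH5 lines, at 1748 ± 873 against 30.5 ± 12.9, as was UTF1, a pluripotency-associated gene, at 78.75 ± 19.7 against 0.75 ± 0.5. WNT targets were lower in the ALKBH5 lines in 12 of 19 cases and higher in 1 (13 and 2 adjusted over the list alone; limma camera adjusted p = 1.83e-05), and definitive endoderm genes in 17 of 20 and higher in 1 (17 and 2 adjusted over the list alone; limma camera adjusted p = 3.16e-17). At day 1 integrated stress response genes were higher in 14 of 15 cases, also adjusted over the list alone (limma camera adjusted p = 1.39e-27).

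In all, 1456 genes were higher and 1498 lower in the ALKBH5 lines at day 1, and 3507 and 4135 at day 3. After median-of-ratios scaling these splits turned to 1632 and 1421, and 4099 and 3567. Beyond the day 0 difference 2451 genes were called at day 1 and 5954 at day 3, 593 and 4067 of them called before in the same direction. Beyond the day 1 difference 4923 were called at day 3, 4212 of them called before in the same direction.

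Genes that changed in both knockouts were counted as well. At day 1, 303 genes rose and 136 fell in both, while 11 and 8 went opposite ways. At day 3, 1776 rose and 1908 fell in both, against 154 and 276 that went opposite ways. Both comparisons use the same 2 wild-type libraries, which cannot be split. Independent lists of these sizes would share 578 and 627.5 at day 3, and part of the excess may come from the shared controls. Simulated unchanged groups shared 0.06 rises and 2.88 falls on average at day 3. Nearly no gene is called in such groups, so they cannot show how far shared controls raise the overlap of long lists. Across genes, which are not independent replicates, the changes correlated at 0.525 at day 1 and 0.535 at day 3. In simulated unchanged groups the correlations were 0.664 and 0.667, a level set by the shared libraries and no yardstick for real changes. The covariance of the changes was 0.102 and 0.332 against 0.069 and 0.0699 in the simulations, a difference of 0.0326 and 0.262. With the DKK4 change taken beyond day 0, 183 genes rose and 120 fell in both at day 1 and 1128 and 1772 at day 3, and beyond day 1 815 and 1008 did at day 3.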

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

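Among the tests reported here, that of mislabelled arm C libraries and that of a library set shared with the 36 h libraries were chosen after the result was seen, as were the differences taken beyond day 0 and day 1.

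The results below stand out because the effect of the ALKBH5 knockout differed between stages or arms by a test of the difference itself. It differed at 5511 genes between day 3 of arm A and day 0, at 1779 genes between arm C and arm A at day 1, and at 5020 genes between the arms at day 3. At day 1 the log2 effect was higher in arm C by 4.22 for EOMES, 1.91 for MIXL1, 2.03 for TBXT, 1.61 for LEF1 and 0.33 for POU5F1. At day 3 it was higher in arm C by 8.20 for DKK4, 7.73 for SOX17, 6.38 for EOMES, 6.26 for FOXA2, 5.78 for MIXL1, 5.61 for GATA6, 4.12 for CXCR4, 3.59 for DKK1 and 0.99 for AXIN2. For POU5F1 and SOX2 the difference was -0.88 and -0.91. A fall of DKK4 could hardly be seen at day 3 of arm C, where both wild-type libraries held 2. The same holds for LEF1 at day 1 of arm A, at 0 and 1 in wild type. The count at day 1 was 1099 without replicate 1 of wild-type arm A day 1.

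The ALKBH5 knockout changed many genes in arm A and few in arm C at day 3. The tables argue against mislabelled arm C knockout libraries, since the highest ALKBH5 value of these 4 libraries was 11 and the lowest in wild type 49. They argue against more spread between replicates in arm C, where the median difference between replicates was 0.789 times that of arm A (0.152 against 0.193). A delay of the arm A knockout cells along the wild-type course would bring them close to an earlier stage. Against the nearest one, day 1, 2290 genes still differed by 2-fold or more, against 3532 at day 3. Against wild-type 36 h the count was 2625, but this comparison crosses the library sets, which may inflate it. This count therefore cannot exclude a delay to near 36 h. The fixed markers argue against it for the genes they cover. EOMES was at 0 to 15 in the knockout at day 3, against 485 and 501 in wild type at 36 h. MIXL1 was at 4 to 23 against 744 and 749, and DKK4 at 0 to 5 against 344 and 346. GATA6, SOX17, FOXA2 and TBXT were lower as well, and CXCR4 was not. These markers too are compared across the library sets. A dependence of the knockout's effect on the culture condition of the arm remains a hypothesis. Its nature stays untested because the labels do not define the arms.

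The DKK4 knockout lines differed from wild type at day 0, where DKK4 was listed at 0 in each library, with 4790 genes called, or 2736 without replicate 1 of wild-type day 0. Scaling of the libraries does not account for the number of genes, with 4454 called after median-of-ratios scaling and 3653 of them shared, but the excess of rises depends on it, 3361 and 1429 before and 2228 and 2226 after a scaling that centres the libraries by construction, while low-level RNA added to these libraries cannot be told apart from a change in the cells. Genes with a mean under 5 rose 0.354 times as often as those at 20 or more, which excludes nothing since low values pass the test less often, and 762 of them rose and 204 fell (597 and 234 after scaling), lincRNAs 158 and 21 (126 and 22). A difference carried by these lines at every stage is consistent with the correlation of 0.506 across the called genes between day 0 and day 1, though genes are not independent replicates and the correlation with day 3 was 0.216, while a library set shared with the 36 h libraries is consistent with 27 of 73 genes apart at 36 h being called at day 0 in that direction and 2 against it. Gain or loss of a whole chromosome stays open. Taking the smaller of both lines, the largest chromosome median was 0.208 over all tested genes (chromosomes 4 and 13), against 0.146 for all genes. The 0.208 lies between the limits set beforehand for and against this cause. Over genes with a mean of 5 or more the largest was 0.273 (chromosome 4). KO1 alone reached 0.268 (chromosome 13) over all tested genes and 0.308 (chromosome 4) at a mean of 5 or more. Lines and library set cannot be told apart here.

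The DKK4 knockout lines also differed from wild type at day 3 of arm A. Over 1963 genes at 2-fold or more, the median share of the log2 change left after subtracting day 0 was 1. A gene listed at 0 at day 0 in these lines gives a share of 1 by construction. Picking genes by a large day 3 change also raises the share. It therefore shows that many larger changes were not seen at day 0, but cannot exclude a difference hidden there by low values. Over all 6416 called genes this share was 0.92, but 3320 of them were called in the same direction beyond day 0 and 67 in the other. The day 0 difference may explain part of the rest. Of the 6416 genes, 2382 were also called in the same direction beyond day 1. A constant shift between library sets would not by itself account for those well above 0 at both stages. For those near 0 at 1 of the stages it need not drop out, and how many these are was not counted. The rest of the 6416 cannot be told apart from such a shift. Of the 73 genes apart at 36 h, 39 were called at day 3 in that direction and 0 against it (21 and 0 at day 1). A shift that grew with the stage may add to all of these, and no library outside the set was made from these lines.

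Between the ALKBH5 and DKK4 knockouts, other splits of the 8 libraries were tried, and they cannot exclude chance differences between lines as the source of the counts. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many genes, with 2839 at day 1 against 385 in the highest other split, and 7859 at day 3 against 3036. Only 3 splits keep both libraries of each line together, too few for a share under 0.05, with 33 and 377 genes in the highest other one. The remaining splits divide the libraries of a line, which raises the spread within a side, so they are no yardstick for the real one. The splits do not separate the knockout from the library set.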

How the results depend on the processing

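The differences beyond day 0 and day 1, the minimum value of 5 and the fit without DKK4 libraries were chosen after the result was seen. All 21 counts stayed within 1.5 times under median-of-ratios scaling, no filter, a pseudocount of 0.1, a minimum value of 5 and the replicate block, which changed no count beyond that limit, and so did the 16 that use no DKK4 library in a fit without those. With only the libraries of the comparison, a fit with fewer residual degrees of freedom and fewer genes tested, the counts were 57 (ALKBH5 day 0), 408 (ALKBH5 arm C day 3), 3077 (DKK4 day 0), and in wild type 300, 3068 and 2595 (arm A day 1, 36 h and day 3), 1575 and 5384 (arm C day 1 and day 3), 2474 and 549 (between arms at day 1 and day 3). KO2 alone gave 248, 821 and 286 for ALKBH5 at day 0, arm A day 1 and arm C day 3, KO1 alone gave 1825 for ALKBH5 arm C day 3 and 829 for DKK4 day 1, and the cause was not tested. At adjusted p below 0.01, a stricter limit by construction, limma called 184, 1003, 1883, 824 and 503 genes for ALKBH5 (day 0, arm A day 1 and 36 h, arm C day 1 and day 3), 2902 and 537 for DKK4 (day 0 and day 1) and 921 for the arm difference at day 1. Beyond day 1, 2688 genes were called for DKK4 day 3 and 4923 between the knockouts. Of genes changed in both knockouts, 183 (day 1) and 1128 (day 3) rose beyond day 0, 815 rose and 1008 fell beyond day 1, and without a filter 211 fell at day 1, and the cause was not tested. Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave 261 to 421 for ALKBH5 day 0, 797 to 1735 for arm A day 1, 1836 to 2756 for 36 h, 905 to 1419 for arm C day 1, 574 to 987 for arm C day 3, 2736 to 4353 for DKK4 day 0, 471 to 1210 for DKK4 day 1, 1254 to 1894 for wild-type arm A day 1 and 1099 to 1693 for the arm difference at day 1. Of 462 list results 203 were called, of which 125 kept the call with an estimated correlation and 78 lost it, and with scaling 184 kept and 19 lost it while 10 others gained it. Among 154 results of named genes, 8 no longer passed with only the libraries of the comparison and 1 newly passed. Of 118 of these results taken with KO1 alone, 7 no longer passed and 2 newly passed. With KO2 alone 6 no longer passed and 1 reversed. The results that reversed in DKK4 were LRRC61 at day 0 with KO2 alone (-2.45), and ID1 (0.58) and RPL36A (-0.19) at day 1 beyond day 0. The cause was not tested. The fall of SOX17 at day 3 in DKK4 was -0.25 with KO1 alone (limma, adjusted p = 0.235). It lost its call beyond day 0 and day 1, where SOX17 was listed at 0, so only its spread grew. Count-based tests were not run, since the values are not counts, and the unknown depth leaves the precision of low values unknown.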

Other observations

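The genes in this part were chosen after their values were seen. In both ALKBH5 lines 10 genes rose at all 6 stages, GPR143, JADE3, PCDHB3, USP9X, LRRC61, CGAS, NQO1, ATP6AP2, ZBED6CL and PDLIM7, and 2 fell, ALKBH5 and CTSF. LRRC61 rose by 1.72 to 3.26 and CGAS, a sensor of DNA in the cytosol, by 0.58 to 1.41 on the log2 scale. LRRC61 and ZBED6CL overlap on chromosome 7, so their values are not independent. GPR143, JADE3, USP9X and ATP6AP2 all lie on chromosome X, and whether their rises are independent of each other was not tested. GPR143 and ATP6AP2 also rose at all 3 stages in the DKK4 lines, by 0.90 to 1.26 and 0.27 to 0.53. The wild-type libraries were the same and the comparison crossed the library sets. Their rise may thus not be particular to the ALKBH5 lines. At day 0 the DKK4 lines lay on opposite sides of wild type for 2 of these genes: LRRC61 was at 30 and 33 in KO1, listed at 0 in both KO2 libraries and at 5 and 4 in wild type, and CTSF was listed at 0 in both KO1 libraries and at 17 in both KO2 libraries, against 10 and 9 in wild type. In the DKK4 lines 205 genes rose and 177 fell at all 3 stages. These comparisons cross the library sets, and a constant shift between the sets would also give such genes. Genes that separate the sets are among them, for example RPL36A, which rose, and BAX, which fell.

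The summed value of 10 metallothionein genes was 911 in wild type at day 0 and 3095 and 4454 in the DKK4 lines, which were also higher at day 1 of arm A (359.5 and 1013 against 305.5) and at day 3 (31 and 25 against 16.5). In the ALKBH5 lines (KO1 and KO2) it was 1070 and 1030 at day 0, and in arm A 230 and 354 at day 1 against 305.5 in wild type, 483.5 and 133 at 36 h against 401.5, and 133.5 and 120 at day 3 against 16.5. In arm C it was 107.5 and 79 at day 1 against 182, and 27.5 and 41.5 at day 3 against 5, so in these lines no direction holds at every stage.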
